A study of Drosophila melanogaster with 54 samples.

How the data were processed

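RNA of sorted cells from Drosophila melanogaster embryos was measured on 54 Affymetrix DrosGenome1 arrays, in 18 groups of 3 arrays. The label of each array gives the genotype, the GFP gate, a numbered set (1, 2 or 3) and a letter. The deposited values are log2 expression summaries per probe set, which the authors made with the affy package, per the submitters' processing notes. No version is stated, nor are the background correction, the normalization and the summary method. The base of the logarithm was inferred from the values, which ran from -3.076 to 13.515. Array medians lay between 4.57 and 4.615 in set 1, 4.166 and 4.272 in set 2, and 3.645 and 3.72 in set 3, so the sets appear to have been normalized separately, and levels were compared only within a set.

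Of the 14010 probe sets, 44 control probe sets were left out of the tests and 13966 were tested, without a filter on low values. They include 12442 with 1 gene symbol, 327 with several and 1197 with none, and cover 10843 genes, of which 1209 have more than 1 probe set. There were 10 missing values. A gene is represented by its probe set with the highest mean over all arrays.

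Each comparison of genotypes was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all arrays of the numbered set (lmFit) and moderated variances with a trend on the mean level (eBayes). Each genotype was compared with the wild type GFP positive arrays of its own set. Arm+Ras with Ras, Pnt with Ras and EGFR with FGFR were compared directly, and Arm+Ras was tested against the sum of the responses to Arm and Ras. GFP positive cells were compared with GFP negative cells over the 18 wild type arrays with the set as a block, and an F test asked whether this difference itself differed between the sets. All p-values are two-sided and were adjusted by the Benjamini-Hochberg method over the probe sets, and adjusted p = 0.05 was the threshold. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.

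The groups, the comparisons, 20 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The lists are founder cell, fusion-competent myoblast, mesoderm, neural, ectoderm with epidermis and trachea, endoderm and yolk, hemocyte and fat body, germ cell, visceral mesoderm, heart and dorsal mesoderm, muscle structural, Notch target, proneural, Ras pathway target, Wg target, Dpp target, heat shock, apoptosis, cell cycle and ribosomal protein genes. Some genes belong to several lists, so the lists are not independent of each other. Each list was tested in each of the 17 comparisons with camera, at a preset correlation of 0.01 and with the correlation estimated from the data, and with fry, and adjusted over the 340 results.

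The genes named in the text follow a rule. They are the genes the genotype mutates or activates, up to 6 genes with the largest rise and up to 6 with the largest fall, every called member of the founder cell and fusion-competent myoblast lists, and up to 4 members with the smallest p of each other list described. The largest changes were taken among called probe sets whose 3 arrays per group did not overlap those of the control, and for the gate within every set. By chance 3 arrays against 3 do not overlap in 10% of cases. Probe sets without a symbol were counted and not named. Where another probe set of a named gene was called in the opposite direction, the text says so. The genes wg, Dl, stumps, arm, Ras85D, pnt and N were not analysed here.

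The calls were tested on simulated arrays, drawn with the means and spreads of the real ones, in which 200 probe sets were changed by known folds. At 2-fold, 47.8% were recovered in the gate comparison, 19.4% (lmd) to 35.8% (FGFR) in a genotype against its wild type, and 11.9% for the departure from the sum of Arm and Ras. At 4-fold the shares ran from 36.4% for that departure to 81.8% for the gate, and at 1.5-fold from 1.49% for Notch to 29.9% for the gate. A probe set without a call may therefore have changed. The number of arrays limits the precision, and no separate collections of embryos are stated.

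Other ways to process the values were the fit without the variance trend, a fit of only the groups compared, the replicate letter as a block, quantile normalization within the set, the brighter probe sets only, a fold threshold, the mean over the probe sets of a gene, each set on its own for the gate, and leaving out each array in turn. For the difference between sets they were quantile normalization over the 18 arrays and centring of each array on its median. The fit without the arrays with the letter A, and the 3′ minus 5′ difference of the eIF-4a control as a covariate in each genotype, were chosen after seeing the control probe sets. Quantile normalization moved the median of all probe sets by no more than 0.05, and each of the 87 called list medians kept its sign. All 54 samples were used.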

Results

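RNA was measured on 54 Affymetrix DrosGenome1 arrays from cells of Drosophila melanogaster embryos. The cells were sorted by fluorescence from embryos in which twi-GAL4 drives UAS-GFP in the mesoderm, the germ layer that gives rise to muscle, heart, fat body and blood cells. Its muscle precursors include founder cells, which carry the identity of a single muscle, and fusion-competent myoblasts, which fuse with founders. The arrays formed 18 groups of 3 in 3 numbered sets, and each set held its own wild type GFP positive and GFP negative cells. Set 1 added activated EGFR, activated FGFR (activated Heartless with Dof) and loss of spi, a ligand gene of EGFR. Set 2 added activated Armadillo (Arm), activated Ras, both together (Arm+Ras), activated Pointed (Pnt), activated Thickveins (Tkv) and loss of wg. Set 3 added loss of Dl, loss of lmd and activated Notch. Embryos were 5.5 to 7.5 h old at 25 °C, except that the 3 genotypes of set 3 were labelled 6 to 8 h against 5.5 to 7.5 h for their wild type.

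The table held 1 log2 value for each of 14010 probe sets and array, and 13966 probe sets were tested. Replicate arrays correlated at r = 0.872 to 0.943 across probe sets, which are not independent replicates. The number of arrays limits the precision, and no label states separate collections of embryos for the replicates, so each p-value measures only the spread between these samples. Levels were compared only within a set, because the array medians differed between sets. The founder cell and fusion-competent myoblast lists may include genes first found with samples of this series, so the direction of these lists is not independent evidence in any comparison given here. Values are log2 fold changes ± SE with 3 arrays per group, and p-values are adjusted over all probe sets tested unless stated otherwise. Counts marked list alone rest on p-values adjusted over the list only. Where a named gene lost its call when 1 array was left out, its highest adjusted p and the array left out for it are given.

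Sorted wild type mesoderm differed from the rest of the embryo in the genes that mark germ layers. Within the GFP positive cells, the myogenic factor twi was higher by 2.87 ± 0.31 (adjusted p = 2.34e-06), the fusion-competent myoblast factor lmd by 3.09 ± 0.29 (adjusted p = 4.1e-07) and the mesodermal gene Him by 2.93 ± 0.26 (adjusted p = 1.42e-07). The segment polarity gene en, expressed in ectoderm, was lower by a log2 fold change of -1.91 ± 0.12 (adjusted p = 1.38e-09), and the epidermal factor grh by -1.90 ± 0.14 (adjusted p = 2.05e-08). The largest rises were Hexo2, a hexosaminidase gene (5.30 ± 0.22, 39.4-fold), Npc2g (4.56), Dgat2 (4.46), the basement membrane gene Ndg (4.13), nAChRbeta3 (4.09) and the hemocyte peroxidasin Pxn (3.97). The largest falls were CG18088 (-3.09), CG43332 (-2.92), CG3349 (-2.81), squ (-2.80), the Hox gene Scr (-2.77) and the linker histone BigH1 (-2.76).

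Among 14 measured mesoderm genes, 10 rose and 1 fell in GFP positive cells (12 and 1 list alone), with camera adjusted p = 4.98e-09. Fusion-competent myoblast genes rose in 4 of 6 cases (6 list alone; camera adjusted p = 1.94e-06), namely lmd, sing (2.49), blow (1.90) and Vrp1 (1.77). The 25 founder cell genes split into 8 that rose and 2 that fell (8 and 2 list alone), and camera called no direction (adjusted p = 0.108). The risers were Ndg, rols (2.93), slou (2.50), org-1 (1.90), nau (1.83), Con (1.68), kirre (1.51) and kn (0.62), and lbl (-1.26) and Dr (-0.50) fell. Hemocyte and fat body genes rose in 11 of 15 cases (11 up and 1 down list alone; camera adjusted p = 1.8e-07), with Ppn at 3.44 and srp, a GATA factor, at 2.72. Visceral mesoderm genes gave 5 rises and 1 fall of 7 (5 and 1 list alone; camera adjusted p = 0.00427), with bap at 1.44 and bin at 1.08. Muscle structural genes gave 2 rises of 12 (2 list alone), Act87E at 0.88 and Mlc1 at 0.97, and camera adjusted p = 0.0199 became adjusted p = 0.0538 with an estimated correlation. Heart and dorsal mesoderm genes gave 2 rises and 3 falls of 12 (2 and 3 list alone), the median (-0.17) and the mean (0.05) differed in sign, and camera called nothing (adjusted p = 0.498).

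Ectoderm, epidermis and trachea genes were lower in GFP positive cells in 12 of 16 cases and higher in 1 (13 and 1 list alone; camera adjusted p = 5.37e-08), with crb at -1.59 and Nrg at -1.14. Neural genes fell in 9 of 16 cases (12 list alone; camera adjusted p = 8.81e-07), with elav at -0.76, and proneural genes in 5 of 7 (6 list alone; camera adjusted p = 5.06e-05), with ac at -2.01 and sc at -1.08. Wg target genes fell in 4 of 5 cases (4 list alone; camera adjusted p = 0.000883), en and nkd (-1.08) among them. Cell cycle genes fell in 12 of 13 cases (12 list alone; camera adjusted p = 5.28e-09), with CycE at -1.21 and PCNA at -0.92. Apoptosis genes fell in 2 of 5 cases, skl (-1.34) and Dronc (-0.68; 5 list alone), and camera adjusted p = 0.00812 became adjusted p = 0.0538 with an estimated correlation. No direction was called for endoderm and yolk genes (1 up, 2 down of 6, and 1 and 2 list alone; camera adjusted p = 0.693) or germ cell genes (1 down of 7, and 1 list alone; 0.426). The same held for Notch target genes (3 up, 7 down of 14, and 3 and 8 list alone; 0.0634), where the mean of 0.03 had the opposite sign to the test, and for Dpp target genes (2 up, 5 down of 12, and 2 and 6 list alone; 0.108). Camera also called nothing for Ras pathway target genes (1 up of 9, and 2 up and 1 down list alone; 0.69), heat shock genes (1 up of 5, and 2 list alone; 0.286) or ribosomal protein genes (1 up, 1 down of 31, and 0 list alone; 0.9). For ribosomal protein genes the median of 0.02 had the opposite sign to the test.

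In total 2332 probe sets differed between GFP positive and GFP negative cells over 18 arrays with the set as a block, 1122 higher and 1210 lower, and 1466 changed by at least 1.5-fold. Of these 2332, 2155 (92.4%) had the same sign in all 3 sets, while 532 also differed in size between the sets. In set 2 every GFP positive array lay below every GFP negative array in the hybridization controls (means 9.32 and 10.23) and in the 3′ minus 5′ signal of eIF-4a (2.13 and 2.33) and GAPDH (0.16 and 0.50), and above in actin (0.92 and 0.79), as in set 3 (1.15 and 0.77), beside each gene group given here. Set 3 alone called 578, against 1601 in set 1 and 1827 in set 2. Of the 70 named genes called, 66 kept the call without any 1 array. Without wild type GFP negative 2A, hkb (adjusted p = 0.0794) lost it, and without wild type GFP negative 1C, bam (0.0611) did. Without wild type GFP negative 2C, slp2 (0.055) lost it, and without wild type GFP positive 2B, RpS29 (0.0925) did.

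Activated EGFR raised founder cell genes and lowered fusion-competent myoblast genes. Of the Egfr probe sets, 1 rose by 3.41 ± 0.14 (adjusted p = 6.17e-09), and the one with the highest mean over all arrays rose by 0.70 ± 0.13 (adjusted p = 0.0074). The adhesion receptor gene kirre, which attracts fusion-competent myoblasts to founders, rose by 2.13 ± 0.22 (adjusted p = 8.69e-05), and phyl by 1.09 ± 0.09 (adjusted p = 1.2e-05). Opposite to these, blow and Vrp1, needed for myoblast fusion, fell by 1.61 ± 0.12 (adjusted p = 4.82e-06) and 2.51 ± 0.38 (adjusted p = 0.00195). Targets of the pathway rose as well: edl by 1.17 ± 0.10, sty, a feedback inhibitor, by 0.91 ± 0.09 and aop by 0.58 ± 0.06.

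Founder cell genes rose in 9 of 25 cases and fell in 1 (12 and 1 list alone; camera adjusted p = 5.37e-08). Besides kirre and phyl these were nau (2.39), Ndg (1.47), kn (1.30), rols (1.26), Kr (1.00), eve (0.84) and org-1 (0.79), and Dr fell by 1.19. Fusion-competent myoblast genes fell in 3 of 6 cases (4 list alone; camera adjusted p = 3.32e-05), lmd by 0.36 ± 0.09 besides blow and Vrp1. Mesoderm genes rose in 5 of 14 cases and fell in 1 (8 and 2 list alone; camera adjusted p = 0.000142), with mib2 at 0.98 and htl at 1.56. Ras pathway target genes rose in 3 of 9 (4 up and 1 down list alone; camera adjusted p = 0.00196). Heat shock genes fell in 2 of 5, DnaJ-1 and Hsp68 (4 list alone; camera adjusted p = 0.00583). Hemocyte and fat body genes gave 2 rises of 15, svp and Pvr (4 up and 1 down list alone), with camera adjusted p = 0.0147 and adjusted p = 0.069 with an estimated correlation. Visceral mesoderm genes gave 2 rises of 7 (3 list alone), with camera adjusted p = 0.0384 and adjusted p = 0.203 with an estimated correlation. Among the largest changes, the rises were PGRP-SC2 (3.10), rst, a relative of kirre (2.75), Arc1 (2.66), nau, obst-H (2.24) and CG8563 (2.24), and the largest falls sug, a zinc finger gene (-3.79), CG32037 (-3.26), Pgm1 (-3.15), rdgBbeta (-3.13), krimp (-3.08) and Gs1 (-2.99).

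Activated EGFR changed 382 probe sets, 182 up and 200 down, and 223 by at least 1.5-fold. The count was 165 without the variance trend, 137 with only the 2 groups compared and 112 without the letter A. Of the 45 named genes called, 33 kept the call without any 1 array. Without EGFR 1C, obst-H (adjusted p = 0.128), Pvr (0.0897) and Hsp68 (0.119) lost it, and without wild type 1B, Kr (0.15) did. Without EGFR 1A, lmd (0.193) lost it, and without wild type 1A, htl (0.061) and svp (0.123) did.

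Activated FGFR gave the same directions in the myoblast lists. The htl gene rose by 1.87 ± 0.32 (adjusted p = 0.00521), kirre by 1.71 ± 0.22 (adjusted p = 0.000647) and phyl by 1.09 ± 0.09 (adjusted p = 1.21e-05). The fusion genes blow and Vrp1 fell by 1.66 ± 0.12 (adjusted p = 4.37e-06) and 2.43 ± 0.38 (adjusted p = 0.00259). Founder cell genes rose in 10 of 25 cases and fell in 1 (12 and 2 list alone; camera adjusted p = 5.17e-06). The others that rose were nau (2.81), the secreted EGFR inhibitor aos (2.81), Ndg (1.69), rols (1.35), kn (1.23), Kr (1.07), eve (0.73) and org-1 (0.67), and Dr fell by 1.40. Fusion-competent myoblast genes fell in 4 of 6 (4 list alone; camera adjusted p = 1.43e-07), with hbs at -0.68 and lmd at -0.50. Ras pathway target genes rose in 4 of 9 (4 list alone; camera adjusted p = 0.000404), with sty at 1.06, edl at 0.96 and aop at 0.48. Mesoderm genes gave 4 rises and 2 falls of 14 (7 and 3 list alone), with camera adjusted p = 0.0196 and adjusted p = 0.0896 with an estimated correlation. Notch target genes gave 4 rises and 1 fall of 14 (6 and 2 list alone), with camera adjusted p = 0.0323 and adjusted p = 0.329 with an estimated correlation. Here E(spl)m2-BFM rose by 0.84 and Tom fell by 0.55.

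The largest rises with activated FGFR were the homeobox gene btn (2.94), nau, aos, Lip4 (2.77), d-cup (2.72) and the homeobox gene H2.0 (2.62), and the largest falls sug (-3.61), Pgm1 (-2.83), gas (-2.77), Ac76E (-2.65), CG6959 (-2.61) and CG32037 (-2.60). It changed 308 probe sets, 172 up and 136 down. The count was 175 without FGFR 1B, 191 without FGFR 1C and 196 without wild type 1C. It was 148 without the variance trend, 148 with only the 2 groups compared, 133 without the letter A and 190 at 1.5-fold or more. Of the 45 named genes called, 28 kept the call without any 1 array. Without FGFR 1B, aos (adjusted p = 0.115), Lip4 (0.136), d-cup (0.0894), gas (0.128), Kr (0.144) and org-1 (0.131) lost it, and without FGFR 1C, CG32037 (0.122) and eve (0.0813) did. Without wild type 1C aos rose by 1.87.

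Compared directly, activated EGFR and activated FGFR differed at 32 probe sets, 12 higher and 20 lower with EGFR, and at 1445 by the unadjusted p. Among the 12 were SLC5A11 (2.44), PGRP-SC2 (2.11), AdamTS-A (1.48), zfh1 (0.80), HnRNP-K (0.56) and Dp1 (0.37). Among the 20 were rdgBbeta (-3.35), CG3097 (-2.38), Grip84 (-1.08), kek5, a relative of the EGFR target kek1 (-1.07 ± 0.13, adjusted p = 0.00405), spidey (-1.02) and CRMP (-0.71). Of the 14 Notch target genes, 1 was lower with EGFR (6 list alone), E(spl)m2-BFM at -0.52, with camera adjusted p = 0.000338 and adjusted p = 0.112 with an estimated correlation. The count was 17 without EGFR 1A, 16 without EGFR 1C, 10 without FGFR 1A, 11 without FGFR 1B and 18 without FGFR 1C. It was 52 with the letter as a block, 8 without the variance trend, 1 with only these 2 groups, 1 without the letter A and 18 at 1.5-fold or more. Of the 14 named genes called, 3 kept the call without any 1 array. Without FGFR 1B, SLC5A11 (adjusted p = 0.132), PGRP-SC2 (0.125), zfh1 (0.125), Grip84 (0.158), spidey (0.0653), CRMP (0.184) and E(spl)m2-BFM (0.133) lost it, and without EGFR 1A, AdamTS-A (0.188) did. Without EGFR 1C, Dp1 (0.11) lost it, and without FGFR 1A, rdgBbeta (0.0594) did.

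Loss of spi did not change the spi probe set (0.00 ± 0.04, adjusted p = 0.995), which does not test the lesion. Of the neural genes, 3 of 16 were called, the homeobox gene pros at -1.24 ± 0.11 (adjusted p = 3.71e-05), the zinc finger gene wor at -0.92 ± 0.12 (adjusted p = 0.000564) and nerfin-1 at -0.72 ± 0.10 (adjusted p = 0.00144). Of the mesoderm list, zfh1 and sna fell by 1.12 ± 0.13 (adjusted p = 0.000344) and 0.72 ± 0.07 (adjusted p = 7.64e-05). The largest changes were in single genes of other kinds. CG11600 rose by 6.27 ± 0.47, Fmo-1 by 5.24, Klp54D by 5.18, CG11854 by 3.93, twz by 3.65 and pdm3 by 3.52. The largest falls were krimp (-3.29, down with EGFR too), Ugt302C1 (-2.99), PCB (-2.96), CG6959 (-2.91, down with FGFR too), Idgf1 (-2.72) and Acp63F (-2.57).

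Neural genes fell in 3 of 16 cases with loss of spi (4 list alone), with camera adjusted p = 0.000322 and adjusted p = 0.1 with an estimated correlation. Of the 25 founder cell genes, Kr fell by 1.03 and none rose (1 list alone; camera adjusted p = 0.447), and 0 of 6 fusion-competent myoblast genes were called (0 list alone; 0.493). Among Ras pathway target genes, 1 of 9 fell, Mkp3 at -0.69 (1 list alone; camera adjusted p = 0.691). Notch target genes fell in 3 of 14 cases (4 list alone; 0.128), with E(spl)mbeta-HLH at -0.54. The chaperone gene DnaJ-1 rose by 0.88, the 1 heat shock gene of 5 called (1 list alone), with camera adjusted p = 0.0418 and adjusted p = 0.108 with an estimated correlation. In all, 445 probe sets changed, 245 up and 200 down. The count was 256, 262 and 232 without spi 1A, 1B and 1C, 295 and 249 without wild type 1A and 1C, 203 without the variance trend, 127 without the arrays with the letter A and 291 at 1.5-fold or more. Of the 29 named genes called, 21 kept the call without any 1 array. Without spi 1B, Ugt302C1 (adjusted p = 0.124) and Acp63F (0.149) lost it, and without wild type 1C, Kr (0.144) did. Without spi 1C, Mkp3 (0.0708) lost it.

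With activated Arm, the effector of Wg signalling, cell cycle and neural genes fell and the myoblast lists were largely uncalled. The cyclin gene CycB3 fell by 1.08 ± 0.10 (adjusted p = 4.86e-07), the replication gene Mcm5 by 1.10 ± 0.13 (adjusted p = 1.44e-05) and wor by 1.49 ± 0.23 (adjusted p = 0.000195). Cell cycle genes fell in 8 of 13 cases (9 list alone; camera adjusted p = 2.14e-09) and neural genes in 3 of 16 (6 list alone; camera adjusted p = 0.00357). Camera called cell cycle genes down with Ras, Arm+Ras, Pnt and wg too (not Tkv), so the shared wild type may be a source. Heat shock genes fell in 1 of 5 cases (5 list alone; camera adjusted p = 0.00266), Hsc70-4 at -0.35 (-0.23 without wild type 2A). Founder cell genes gave 1 rise, H15 (0.74), and 1 fall, kn (-1.15), of 25 (2 and 1 list alone; camera adjusted p = 0.687). None of 6 fusion-competent myoblast genes (0 list alone; camera adjusted p = 0.605) or 5 Wg target genes (0 list alone; 0.861) was called. The Wg target median of -0.17 and mean of 0.105 differed in sign. Notch target genes split into 2 rises and 3 falls of 14 (3 and 4 list alone; 0.828), with Kaz-m1 at 1.26 and E(spl)m4-BFM at -1.14. Their median of 0.12 and mean of 0.01 had the opposite sign to that test.

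The largest rises with activated Arm were the ionotropic receptor gene Ir64a (6.08 ± 0.51), CG13794 (4.24), CG8958 (3.53), CG4704 (2.88), t-Grip91 (2.85) and Marc (2.76), and the largest falls Fem-1 (-3.28), CG7966 (-3.14), ana3 (-3.10), CG3430 (-3.09), CG15160 (-2.95) and the innexin gene Inx7 (-2.94). It changed 966 probe sets, 356 up and 610 down. Hybridization controls averaged 9.99 (SD 0.34, n = 3) against 9.32 (SD 0.27, n = 3) in the wild type of set 2, and the actin 3′ minus 5′ signal 1.17 against 0.92, beside each gene group with Arm. The count was 639 without wild type 2A, 408 with only the 2 groups compared and 558 without the letter A. Of the 35 named genes called, 26 kept the call without any 1 array. Without wild type 2A, t-Grip91 (adjusted p = 0.129), kn (0.102), H15 (0.207) and Hsc70-4 (0.306) lost it, and without Arm 2C, CG7966 (0.0651) did.

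Activated Ras raised founder cell, mesoderm and pathway target genes. The transcriptional repressor gene aop rose by 1.68 ± 0.14 (adjusted p = 1.84e-07), edl by 1.17 ± 0.10 (adjusted p = 1.64e-07) and sty by 1.08 ± 0.20 (adjusted p = 0.00205). The founder gene rols, which links the fusion receptors to the cytoskeleton, rose by 1.85 ± 0.34 (adjusted p = 0.00173), and blow fell by 1.05 ± 0.10 (adjusted p = 9.88e-07). The collagen gene vkg rose by 3.42 ± 0.66 (adjusted p = 0.00266) and the laminin gene LanA by 0.81 ± 0.15 (adjusted p = 0.00215). Founder cell genes rose in 7 of 25 cases (8 list alone; camera adjusted p = 4.04e-05), with nau at 2.51, kn at 1.96, org-1 at 1.70, Ndg at 1.08, phyl at 0.78 and eve at 0.72 besides rols. For fusion-competent myoblast genes, blow was the 1 fall of 6 (2 list alone; camera adjusted p = 0.186).

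Mesoderm genes rose in 4 of 14 cases with activated Ras (8 list alone; camera adjusted p = 7.1e-06), with htl at 1.64. Hemocyte and fat body genes rose in 6 of 15 (8 list alone; camera adjusted p = 2.01e-09), with Ppn at 2.35 and LanB1 at 0.77. Ras pathway target genes rose in 4 of 9 (4 list alone; camera adjusted p = 1.44e-05). Notch target genes rose in 6 of 14 and fell in 1 (10 and 2 list alone; camera adjusted p = 4.22e-07), with E(spl)m4-BFM at 0.98. Cell cycle genes fell in 4 of 13 (5 list alone), Mcm5 by 1.00, with camera adjusted p = 0.000465 and adjusted p = 0.0678 with an estimated correlation. Named by size, the rises were CG14957 (4.06), vkg, the lysozyme LysC (3.15), CG31248 (3.07), mwh (3.05) and Lip4 (2.73), and the largest falls Pgm1 (-3.88), thw (-3.09), CG11158 (-3.07), gol (-2.90, and -1.79 without Ras 2C), CG11597 (-2.77) and sug (-2.57). Activated Ras changed 641 probe sets, 345 up and 296 down, with a 3′ minus 5′ signal of 0.75 against 0.92 for actin and -0.02 against 0.16 for GAPDH beside each group. The count was 394 without the variance trend, 374 without the letter A and 406 at 1.5-fold or more. Of the 46 named genes called, 34 kept the call without any 1 array. Without wild type 2C, CG31248 (adjusted p = 0.19) and eve (0.0774) lost it, and without wild type 2B, CG11158 (0.0567) did. Without Ras 2B, CG11597 (0.0592) and sug (0.115) lost it, and without Ras 2C, nau (0.0521) did. Without Ras 2A, phyl (0.103) lost it.

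Arm and Ras activated together raised founder cell genes in 8 of 25 cases. The founder gene Ndg rose by 1.56 ± 0.23 (adjusted p = 0.000305), phyl by 1.39 ± 0.19 (adjusted p = 0.000149) and rols by 1.74 ± 0.34 (adjusted p = 0.00498). The fusion gene blow fell by 1.54 ± 0.10 (adjusted p = 4.2e-09) and Vrp1 by 2.86 ± 0.66 (adjusted p = 0.0197). The receptor gene htl rose by 1.95 ± 0.32 (adjusted p = 0.00102) and the EGFR target kek1 by 2.78 ± 0.51 (adjusted p = 0.00279). Adjusted over the list alone, the founder count was 9 up and 1 down (camera adjusted p = 1.67e-09), and the other risers were slou (2.55), Kr (2.44), nau (2.28), org-1 (1.23) and eve (0.95). For fusion-competent myoblast genes, these 2 were the falls of 6 (2 list alone; camera adjusted p = 0.00231, and adjusted p = 0.0696 with an estimated correlation).

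Mesoderm genes rose in 4 of 14 cases with Arm+Ras (8 list alone; camera adjusted p = 2.94e-08), with mib2 at 1.21. Hemocyte and fat body genes rose in 5 of 15 (11 list alone; camera adjusted p = 5.56e-12), vkg at 3.72 and Ppn at 1.52 among them, and Ras pathway target genes in 4 of 9 (4 list alone; camera adjusted p = 1.28e-07). Visceral mesoderm genes rose in 2 of 7, jeb (2.24) and org-1 (3 list alone; camera adjusted p = 0.000606). No heat shock gene of 5 was called (3 down list alone; camera adjusted p = 0.00812). Cell cycle genes fell in 2 of 13, Mcm5 at -0.73 and PCNA at -0.36 (4 list alone), with camera adjusted p = 0.00311 and adjusted p = 0.112 with an estimated correlation. By size, the first rises were vkg, CG14957 (3.37), kek1, CG8507 (2.70), Lip4 (2.57) and slou, and the largest falls thw (-3.21), Vrp1, gas (-2.45), Inx7 (-2.44), sug (-2.35) and Pgm1 (-2.33). Together 338 probe sets changed, 192 up and 146 down, while hybridization controls averaged 9.84 (SD 0.07, n = 3). The count was 219 without Arm+Ras 2C, 199 without the variance trend, 170 without the letter A and 219 at 1.5-fold or more. Of the 44 named genes called, 22 kept the call without any 1 array. Without wild type 2C, CG8507 (adjusted p = 0.219), slou (0.155), Vrp1 (0.102) and PCNA (0.12) lost it, and without Arm+Ras 2B, gas (0.216) and Inx7 (0.172) did. Without Arm+Ras 2C, sug (0.269), Pgm1 (0.137), nau (0.146), org-1 (0.128) and jeb (0.108) lost it, and without wild type 2B, Kr (0.178) did.

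Against Ras alone, Arm+Ras raised the secreted Wg antagonist Notum by 3.50 ± 0.67 (adjusted p = 0.00638) and kek1 by 2.26 ± 0.51 (adjusted p = 0.0234). Notch target genes fell in 6 of 14 cases (9 list alone; camera adjusted p = 7.55e-09), with E(spl)m4-BFM at -0.79 ± 0.12, E(spl)m7-HLH at -0.49 and Tom at -0.33. Of the 5 Wg target genes, Notum rose (1 list alone), with camera adjusted p = 0.0128 and adjusted p = 0.0922 with an estimated correlation. For founder cell genes, kn was lower by 1.33 and none of 25 was higher (1 list alone; camera adjusted p = 0.224), and for fusion-competent myoblast genes blow was lower at -0.50 (2 of 6 list alone; camera adjusted p = 0.0593). The other large rises were CG7730 (3.72), CG16815 (3.23), Galphaq (3.11), Uhg1 (2.79) and the mesodermal homeobox gene Six4 (2.48), and the largest falls mwh (-3.28), LysC (-3.01), CG9338 (-2.93), CG10177 (-2.87), Jon99Fi (-2.57) and LysD (-2.48). The eIF-4a 3′ minus 5′ signal averaged 1.98 against 2.26 with Ras, beside these groups. There were 224 calls, 106 up and 118 down. The count was 147 without Arm+Ras 2B, 119 without Arm+Ras 2C, 132 without Ras 2C, 95 without the variance trend, 133 without the arrays with the letter A and 127 at 1.5-fold or more. Of the 24 named genes called, 14 kept the call without any 1 array. Without Arm+Ras 2C, CG16815 (adjusted p = 0.186), Uhg1 (0.105) and blow (0.0571) lost it, and without Ras 2A, Galphaq (0.2) did. Without Ras 2B, Six4 (0.164) and kek1 (0.119) lost it, and without Arm+Ras 2B, Jon99Fi (0.0704) and kn (0.0893) did. Without Ras 2C, Tom (0.0682) lost it.

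Arm+Ras departed from the sum of the single responses at 620 probe sets, 328 above it and 292 below. Cell cycle genes lay above the sum, with PCNA at 0.95 ± 0.11 (adjusted p = 3.43e-05), Mcm5 at 1.37 ± 0.19 (adjusted p = 0.000141) and CycB at 0.75 ± 0.12 (adjusted p = 0.000651). These genes were each lower with Arm alone, and PCNA and Mcm5 were lower with Ras alone. The shared wild type enters this contrast too, so wild type arrays high in these genes would also place them above the sum. That was not tested. The count was 5 of 13 cell cycle genes above the sum (9 list alone; camera adjusted p = 1.63e-08). Notch target genes lay below it in 5 of 14 cases (5 down and 1 up list alone), with E(spl)malpha-BFM at -0.92, and camera adjusted p = 0.00812 became adjusted p = 0.112 with an estimated correlation. The largest departures above were swa (4.27), CG3430 (4.23), CG1024 (4.03), CG7730 (4.01), RecQ4 and ana3 (3.97), and those below Ir64a (-6.66), LysC (-4.04), CG13794 (-3.92), CG3528 (-3.79), CG6083 (-3.77) and CG8958 (-3.76). The fusion gene blow was lower than the sum by 0.51, the 1 call of 6 fusion-competent myoblast genes (1 list alone; camera adjusted p = 0.543), with a median of -0.17 and a mean of 0.01. The count was 332 without the variance trend and 343 without the letter A. Of the 31 named genes called, 23 kept the call without any 1 array. Without wild type 2A, CG1024 (adjusted p = 0.137) and blow (0.104) lost it, and without Arm+Ras 2C, RecQ4 (0.0967) did.

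With activated Pnt, an ETS factor downstream of Ras, pathway target genes rose and ectodermal and cell cycle genes fell. Its largest pathway change was in edl, which rose by 2.06 ± 0.10 (adjusted p = 2.02e-11), and aop rose by 0.91 ± 0.14 (adjusted p = 0.000117). The ectodermal gene en fell by 2.02 ± 0.31 (adjusted p = 0.000123), the E-cadherin gene shg by 1.72 ± 0.41 (adjusted p = 0.00874; 0.96 without Pnt 2A) and CycB by 0.89 ± 0.09 (adjusted p = 4.87e-07). Founder cell genes went both ways, with 4 rises and 2 falls of 25 (5 and 2 list alone; camera adjusted p = 0.848), Ndg at 1.60, rols at 1.10, H15 at 0.72, eve at 0.60, Con at -3.05 and Dr at -2.38. Their median of -0.13 and mean of -0.21 had the opposite sign to the test. Vrp1, at -3.04 ± 0.66 (adjusted p = 0.004), was the 1 fusion-competent myoblast gene of 6 called (1 list alone; camera adjusted p = 0.732).

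Ectoderm, epidermis and trachea genes fell in 6 of 16 cases with activated Pnt (11 list alone; camera adjusted p = 2.03e-05) and cell cycle genes in 7 of 13 (9 list alone; camera adjusted p = 8.46e-08). Heat shock genes fell in 4 of 5 (4 list alone; camera adjusted p = 0.000133), DnaJ-1 by 0.76, and Dpp target genes in 4 of 12 (4 list alone; camera adjusted p = 0.0177), Doc3 by 2.44. Ras pathway target genes rose in 3 of 9 (4 list alone; camera adjusted p = 0.00378). Wg target genes fell in 1 of 5, en (2 list alone), with camera adjusted p = 0.0456 and adjusted p = 0.171 with an estimated correlation. Of 31 ribosomal protein genes, 11 rose and 6 fell (15 and 6 list alone; camera adjusted p = 0.135). Rises were largest for CG4250 (3.50), btn (3.31), CG30195 (3.26), CG3349 (3.07), CG31248 (3.01) and twz (2.97), and the largest falls the serpin Spn43Aa (-3.84), thw (-3.33), LManII (-3.10), mol (-3.09), Inx7 (-3.07) and Con. Activated Pnt changed 1236 probe sets, 541 up and 695 down, while hybridization controls averaged 10.18 (SD 0.19, n = 3) and the 3′ minus 5′ signal 1.22 against 0.92 for actin and -0.71 against 0.16 for GAPDH, beside each group. The count was 713 with only the 2 groups compared and 734 without the letter A. Of the 55 named genes called, 36 kept the call without any 1 array. Without wild type 2A, CG3349 (adjusted p = 0.13) and H15 (0.185) lost it, and without wild type 2C, CG31248 (0.135) did. Without Pnt 2C, mol (0.054), Con (0.176) and eve (0.176) lost it, and without Pnt 2A, rols (0.129) did.

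Between activated Pnt and activated Ras, founder cell genes were lower with Pnt in 5 of 25 cases (6 list alone; camera adjusted p = 0.00134), Con by 4.02, slou by 2.20, org-1 by 2.10 ± 0.31, Dr by 1.58 (0.84 without Pnt 2B) and kn by 1.54 ± 0.29. The fusion-competent myoblast gene blow was higher by 1.25 ± 0.10 (adjusted p = 4.2e-08) and lmd lower by 0.91, which gave 1 up and 1 down of 6 (1 and 1 list alone; camera adjusted p = 0.697). The median of -0.12 and mean of -0.08 of these 6 genes had the opposite sign to the test. Of the pathway targets, edl was higher by 0.88 ± 0.10 and aop lower by 0.77 ± 0.14, so 1 of 9 rose and 1 fell (1 and 1 list alone; camera adjusted p = 0.69). Lower with Pnt were hemocyte and fat body genes in 7 of 15 cases (10 list alone; camera adjusted p = 1.83e-06), ectoderm, epidermis and trachea genes in 5 of 16 (5 list alone; 0.0002), mesoderm genes in 3 of 14 (3 list alone; 0.0086) and endoderm and yolk genes in 2 of 6 (3 list alone; 0.00583). Camera calls lost with an estimated correlation were those of Notch target genes (1 up and 6 down of 14, and 1 and 7 list alone; adjusted p = 0.00129, then adjusted p = 0.0603 with an estimated correlation), neural genes (5 down of 16, and 5 down and 1 up list alone; 0.0172, then 0.0896) and heat shock genes (1 down of 5, and 4 list alone; 0.018, then 0.0659). The largest rises were CG4250 (3.12), Ugt37C2 (3.08), Pgm1 (3.04), CG14022 (2.90), CG7730 (2.75) and NimB1 (2.67), and the largest falls the snail-family gene esg (-4.19), Con, CG9338 (-3.82), mwh (-3.52), LManII (-3.48) and CG2233 (-3.40). Beside these groups, every Pnt array lay above every Ras array in the actin 3′ minus 5′ signal (1.22 and 0.75) and below in eIF-4a (2.14 and 2.26) and GAPDH (-0.71 and -0.02). There were 1365 calls, 573 up and 792 down, and 873 without the letter A. Of the 52 named genes called, 38 kept the call without any 1 array. Without Pnt 2B, slou (adjusted p = 0.113) and Dr (0.0545) lost it, and without Ras 2B, lmd (0.0869) did.

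Activated Tkv, the Dpp receptor, raised Dpp target genes. The tkv gene rose by 4.04 ± 0.17 (adjusted p = 1.03e-11), while its other probe set was at 1.61 (adjusted p = 0.167). The inhibitory Smad gene Dad rose by 2.37 ± 0.27 (adjusted p = 8.87e-06), the T-box gene Doc1 by 1.53 ± 0.15 (adjusted p = 2.05e-06), and the visceral mesoderm factors bin and bap by 1.73 ± 0.23 (adjusted p = 5.13e-05) and 1.48 ± 0.20 (adjusted p = 6.18e-05). Dpp target genes rose in 8 of 12 cases and fell in 1 (9 and 1 list alone; camera adjusted p = 1.07e-08). Hemocyte and fat body genes rose in 7 of 15 (8 list alone; camera adjusted p = 4.22e-07), with Ppn at 2.04 and ush at 1.89. Fusion-competent myoblast genes rose in 2 of 6, hbs (1.55) and blow (0.51 ± 0.10; 3 list alone), with camera adjusted p = 0.00427 and adjusted p = 0.0901 with an estimated correlation. Founder cell genes gave 1 rise, the receptor gene Alk (3.05), and 1 fall, slou (-2.29), of 25 (3 and 1 list alone; camera adjusted p = 0.825).

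Visceral mesoderm genes gave 3 rises and 1 fall of 7 with activated Tkv (4 and 1 list alone), with camera adjusted p = 0.0176 and adjusted p = 0.0503 with an estimated correlation. Mesoderm genes gave 3 rises and 1 fall of 14 (4 and 1 list alone; 0.0323, then adjusted p = 0.0626 with an estimated correlation). Heart and dorsal mesoderm genes gave 4 rises and 2 falls of 12 (5 and 2 list alone; 0.0442, then adjusted p = 0.0802 with an estimated correlation), with pnr at 1.21 and odd at -0.99. Ribosomal protein genes fell in 9 of 31 cases and rose in 1 (12 and 3 list alone; camera adjusted p = 0.189). Rises were largest for the small nucleolar RNA host gene Uhg1 (4.77), tkv, CG8607 (3.83), Mical (3.72), AdamTS-B (3.49) and CG2519 (3.37), and the largest falls Coq8 (-4.47), Spn43Aa (-3.33), the segmentation gene gsb (-3.12), Kif3C (-2.81), CG13716 (-2.58) and magu (-2.53). It changed 1170 probe sets, 619 up and 551 down. In the Tkv arrays the 3′ minus 5′ signal averaged 1.81 for the eIF-4a control against 2.13 in the wild type, 0.58 for actin against 0.92 and -0.56 for GAPDH against 0.16 (n = 3 each), beside each gene group of this comparison. With the eIF-4a difference as a covariate the count was 563. It was 774 without Tkv 2A, 771 without Tkv 2C, 729 without wild type 2B and 706 without wild type 2C. Of the 45 named genes called, 31 kept the call without any 1 array. Without Tkv 2C, Kif3C (adjusted p = 0.0514) lost it, and without Tkv 2B, CG13716 (0.206) did. Without wild type 2B, slou (0.134) and hbs (0.12) lost it, and without wild type 2A, Alk (0.11) did. Without wild type 2C, pnr (0.0634) lost it, and without Tkv 2A, odd (0.115) did.

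Loss of wg changed 3709 probe sets or 26.56% of all, 1541 up and 2168 down, the highest count of a genotype here. With the eIF-4a 3′ minus 5′ covariate it was 793 (Pnt 1321, Arm 1226). That covariate nearly coincides with loss of wg, so the 793 ranks nothing. The Wg target en fell by 3.13 ± 0.31 (adjusted p = 7.07e-08), and slou, a founder factor, by 2.30 ± 0.59 (adjusted p = 0.00535). The founder factor kn rose by 2.13 ± 0.29 (adjusted p = 7.13e-06) and the cardiac and visceral factor Hand by 2.80 ± 0.62 (adjusted p = 0.00154). Cell cycle genes fell, CycB by 1.59 ± 0.09 (adjusted p = 7.74e-12). Beside each gene group, the eIF-4a 3′ minus 5′ signal averaged 3.40 (SD 0.17, n = 3) against 2.13 (SD 0.12, n = 3) in the wild type. That of actin was 1.38 against 0.92, that of GAPDH 1.17 against 0.16, and hybridization controls 10.99 (SD 0.17, n = 3) against 9.32 (SD 0.27, n = 3).

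Founder cell genes gave 3 rises and 5 falls of 25 with loss of wg (3 and 5 list alone; camera adjusted p = 0.996). Besides kn these were H15 (1.24) and eve (0.84) upwards, and Ndg (-2.79), aos (-2.72), slou, Kr (-1.99) and rols (-1.35, and -0.80 without wg 2B) downwards. Fusion-competent myoblast genes gave 1 fall of 6, sing at -0.79 (0 list alone; camera adjusted p = 0.856), with a median of 0.004 and a mean of -0.07, which differed in sign. Cell cycle genes fell in 10 of 13 cases and rose in 1 (10 and 1 list alone; camera adjusted p = 5.66e-06), the 1 list called. Wg target genes fell in 2 of 5, en and slp2 (3 list alone; 0.173), and ectoderm, epidermis and trachea genes in 5 of 16 (5 down and 1 up list alone; 0.234). Muscle structural genes gave 4 rises and 1 fall of 12 (4 and 1 list alone; 0.362), TpnC73F at 3.38, Mlc1 at 2.93 and Act87E at -1.37. Ribosomal protein genes went both ways, 12 up and 13 down of 31 (12 and 13 list alone; 0.826), from RpL36A at 1.00 to RpS5b at -2.40, with a median of 0.22 and a mean of -0.07, which differed in sign. The genes nub and Ppn fell by 2.48 and 1.68, and another probe set of each was called in the opposite direction.

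The largest rises with loss of wg were Uhg1 (5.97), CG4565 (5.74), beat-Vb (5.60), CG2574 (5.59), CG34281 (4.15) and Gbp2 (3.95), and the largest falls Hexo2 (-4.73), the nucleoporin gene Nup107 (-4.42), gsb (-4.27), the exocyst gene Sec5, fliI (-3.97) and CG1824 (-3.92). With the 3′ minus 5′ difference as a covariate, rols (1.16), aos (0.73), sna (0.03) and Mkp3 (-0.84) changed sign. Of the 66 named genes called, 56 kept the call without any 1 array. Without wild type 2C, Kr (adjusted p = 0.0968) and sing (0.136) lost it, and without wg 2A, sna (0.0714) did. Without wg 2C, slp2 (0.152) lost it.

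**Figure D1:**
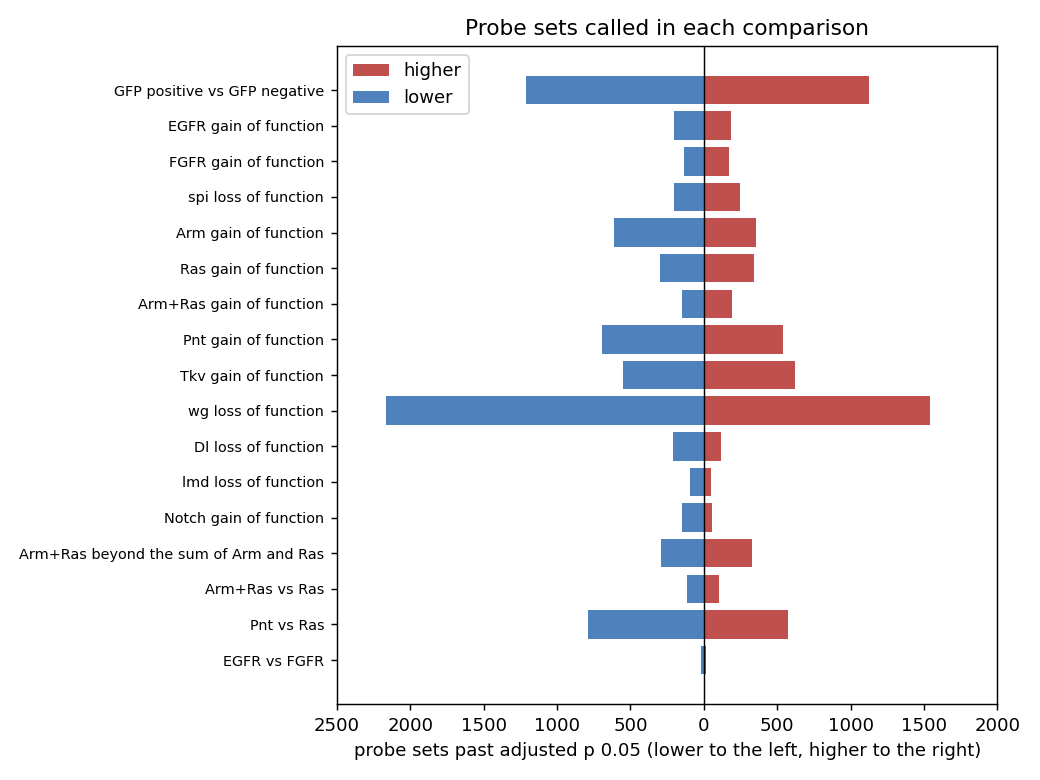
Number of probe sets past adjusted p = 0.05 (horizontal axis, lower to the left and higher to the right) in each comparison (vertical axis). Loss of wg has the highest count, 3709, and EGFR against FGFR the lowest, 32.

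**Figure D2:**
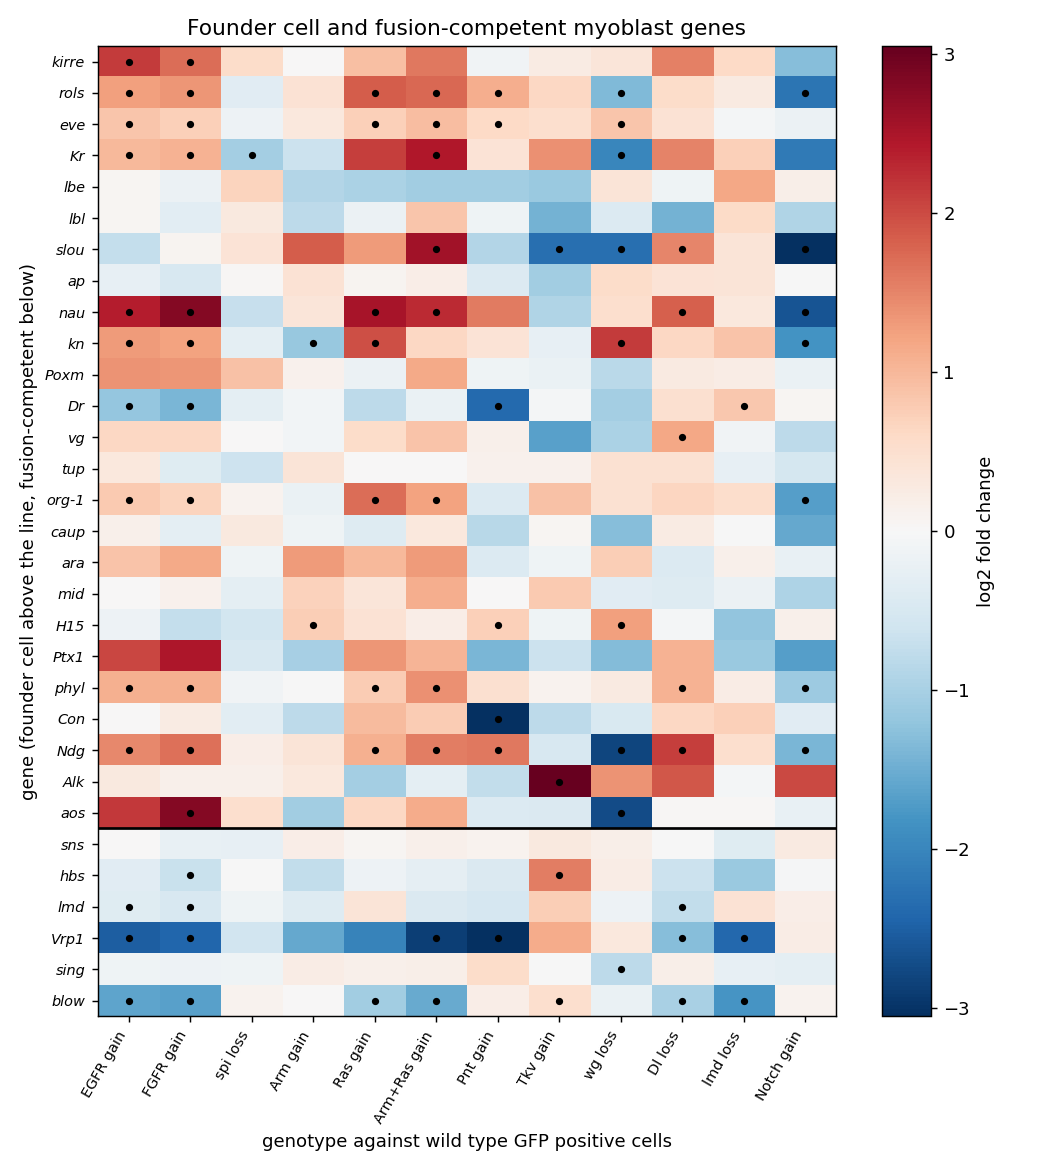
Log2 fold change (colour) of founder cell genes above the line and fusion-competent myoblast genes below it, in each genotype against the wild type GFP positive cells of its set, with a dot where adjusted p was below 0.05. The gene blow is lower with EGFR (-1.61), FGFR (-1.66), Ras (-1.05), Arm+Ras (-1.54), loss of lmd (-1.79) and loss of Dl (by 1.00).

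With loss of Dl, a ligand gene of Notch, Notch target genes fell and founder cell and neural genes rose. Carry-over of GFP negative cells, where neural genes were higher, was tested only for loss of wg. The target genes E(spl)mbeta-HLH and E(spl)malpha-BFM fell by 2.08 ± 0.14 (adjusted p = 1.3e-06) and 1.37 ± 0.09 (adjusted p = 1.3e-06). The founder gene Ndg rose by 2.11 ± 0.28 (adjusted p = 0.000736), and the neuroblast genes insc and wor by 1.63 ± 0.22 (adjusted p = 0.000942) and 1.31 ± 0.17 (adjusted p = 0.000641). The fusion-competent myoblast genes Vrp1 and blow fell by 1.30 ± 0.20 (adjusted p = 0.00207) and 1.00 ± 0.17 (adjusted p = 0.00411), and sna rose by 1.47 ± 0.09 (adjusted p = 6.54e-07). The eIF-4a 3′ minus 5′ difference averaged 3.40 (SD 0.50, n = 3) against 2.61 (SD 0.22, n = 3) in the wild type of set 3, and that of actin 1.78 against 1.15, beside each of these groups.

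Notch target genes fell in 11 of 14 cases with loss of Dl (13 list alone; camera adjusted p = 1.71e-24). Founder cell genes rose in 5 of 25 (11 list alone; camera adjusted p = 1.28e-07), nau at 1.83, slou at 1.49, vg at 1.17 and phyl at 1.07 besides Ndg. Fusion-competent myoblast genes fell in 3 of 6 (3 list alone), lmd by 0.74, with camera adjusted p = 0.000571 and 0.0574 with an estimated correlation. Neural genes rose in 5 of 16 (6 list alone; camera adjusted p = 2.08e-06), and cell cycle genes in 2 of 13, Mcm5 at 1.04 and E2f1 at 0.46 (9 list alone; camera adjusted p = 9.11e-07). Heat shock genes fell in 3 of 5 (3 list alone; camera adjusted p = 0.00199), Hsp68 by 1.23. Mesoderm genes gave 4 rises and 2 falls of 14 (6 and 2 list alone; camera adjusted p = 0.0315, and 0.1 with an estimated correlation). No visceral mesoderm gene of 7 was called (2 up list alone; camera adjusted p = 0.049, and 0.132 with an estimated correlation). Rises were largest for CG8564 (4.99), CG17752 (3.67), CG8562 (3.59), rdgC (2.56), CG11313 (2.48) and CG13840 (2.21), and the largest falls CG42324 (-3.44), nkt (-3.04), Cyp6d2 (-3.04), Hsp26 (-2.98), Pdrg1 (-2.95) and the metallothionein MtnA (-2.87). Of these, CG13840, nkt and MtnA changed the same way with loss of lmd and activated Notch.

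Loss of Dl changed 331 probe sets, 120 up and 211 down. The count was 199 without Dl 3B, 205 without Dl 3C, and 208, 179 and 172 without wild type 3A, 3B and 3C. It was 709 with the letter as a block and 744 with the 3′ minus 5′ difference as a covariate, but 127 without the variance trend and 168 with only the 2 groups compared. Of the 42 named genes called, 27 kept the call without any 1 array. Without wild type 3C, CG17752 (adjusted p = 0.0567), CG11313 (0.0853), Hsp26 (0.0505) and nau (0.0571) lost it, and without wild type 3B, rdgC (0.0655), Pdrg1 (0.0841) and E2f1 (0.118) did. Without Dl 3C, slou (0.158) and phyl (0.16) lost it, and without Dl 3B, vg (0.108) did.

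Activated Notch gave the opposite direction in both groups, raising Notch target genes and lowering founder cell genes. The target genes Kaz-m1 and E(spl)m5-HLH rose by 2.43 ± 0.15 (adjusted p = 7.27e-07) and 1.61 ± 0.10 (adjusted p = 7.27e-07). The founder genes rols and slou fell by 2.23 ± 0.16 (adjusted p = 1.41e-06) and 3.03 ± 0.36 (adjusted p = 0.00038). The neural genes fne and nerfin-1 fell by 1.46 ± 0.19 (adjusted p = 0.000834) and 1.38 ± 0.24 (adjusted p = 0.00686), and the chaperone gene Hsp68 by 1.86 ± 0.12 (adjusted p = 7.27e-07). Beside these groups, the eIF-4a 3′ minus 5′ difference averaged 3.21 (SD 0.28, n = 3) against 2.61 (SD 0.22, n = 3), that of GAPDH 2.67 against -0.47 and that of actin 1.46 against 1.15.

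Notch target genes rose in 11 of 14 cases with activated Notch (13 list alone; camera adjusted p = 1.12e-28). Founder cell genes fell in 7 of 25 (10 down and 1 up list alone; camera adjusted p = 1.72e-09), nau by 2.63, kn by 1.82, org-1 by 1.67 (1.07 without Notch 3C), Ndg by 1.39 and phyl by 1.11 besides rols and slou. Of the 6 fusion-competent myoblast genes none was called (0 list alone; camera adjusted p = 0.526). Neural genes fell in 5 of 16 (7 list alone; camera adjusted p = 7.9e-06) and heat shock genes in 3 of 5 (4 list alone; camera adjusted p = 4.97e-09). Muscle structural genes gave 1 rise of 12, Mlc2 at 0.98 (2 list alone; camera adjusted p = 0.0041). Hemocyte and fat body genes gave 1 rise of 15, gcm at 0.59, which also rose with loss of Dl and of lmd (2 up and 5 down list alone), and the list itself went down, with camera adjusted p = 0.0242 and adjusted p = 0.145 with an estimated correlation. Dpp target genes gave 1 fall of 12, Ance at -0.68 (1 up and 3 down list alone), with camera adjusted p = 0.0395 and adjusted p = 0.0953 with an estimated correlation.

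The largest rises with activated Notch were CG12885 (4.10), CG5177 (3.80), CG3515 (3.18), Pde6 (2.84), CG14314 (2.61) and Oat (2.47), and the largest falls tey, a muscle gene (-4.21), Muc12Ea (-4.19), H2.0 (-4.12), the matrix protease Mmp2 (-3.12), slou and Cdc14 (-2.87). It changed 207 probe sets, 59 up and 148 down. The count was 128 without wild type 3B and 123 without wild type 3C, 424 with the letter as a block, 686 with the 3′ minus 5′ difference as a covariate, 125 without the variance trend and 91 with only the 2 groups compared. Of the 38 named genes called, 25 kept the call without any 1 array. Without wild type 3B, CG12885 (adjusted p = 0.119), Pde6 (0.0744), org-1 (0.127), phyl (0.185) and Ndg (0.107) lost it, and without wild type 3C, CG14314 (0.0518) did. Without Notch 3B, Mmp2 (0.142) lost it, and without wild type 3A, Cdc14 (0.148) did.

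Loss of lmd, whose product specifies fusion-competent myoblasts, lowered genes of that list. The lmd probe set itself was at 0.44 ± 0.12 (adjusted p = 0.149), which does not test the lesion. The fusion genes Vrp1 and blow fell by 2.40 ± 0.20 (adjusted p = 2.45e-05) and 1.79 ± 0.17 (adjusted p = 5.79e-05), and ptc, the Hedgehog receptor gene, by 2.52 ± 0.36 (adjusted p = 0.00259). The mesodermal gene gol fell by 2.65 ± 0.36 (adjusted p = 0.00171). The eIF-4a 3′ minus 5′ difference stood at 3.43 (SD 0.56, n = 3) against 2.61 (SD 0.22, n = 3), and that of actin at 1.91 against 1.15, beside these genes. Fusion-competent myoblast genes fell in 2 of 6 cases (4 down and 1 up list alone; camera adjusted p = 3.83e-05). Founder cell genes gave 1 rise of 25, Dr at 0.83 (2 list alone; camera adjusted p = 0.0142). Mesoderm genes gave 1 rise of 14, Him at 0.52 (5 up and 1 down list alone), with camera adjusted p = 0.00787 and adjusted p = 0.0538 with an estimated correlation. No visceral mesoderm gene of 7 was called (0 list alone; camera adjusted p = 0.0262, and 0.0986 with an estimated correlation). Notch target genes gave 1 rise and 1 fall of 14 (3 and 1 list alone; camera adjusted p = 0.151).

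The largest rises with loss of lmd were Spn28Db (4.81), the dynein gene Dhc98D (4.04), Pde6 (2.98), rdgC (2.90), CG8870 (2.75) and CG3857 (2.03), and the largest falls Cyp6d2 (-4.28), mthl4 (-3.50), nkt (-3.47), CG13833 (-2.77), the clock gene tim (-2.76) and gol. Of these, nkt also fell with loss of Dl and activated Notch. It changed 144 probe sets, 51 up and 93 down. The count was 89 without lmd 3C, 70 and 71 without wild type 3B and 3C, 385 with the letter as a block, 634 with the 3′ minus 5′ difference as a covariate, 70 without the variance trend and 38 with only the 2 groups compared. Of the 21 named genes called, 10 kept the call without any 1 array. Without wild type 3B, Pde6 (adjusted p = 0.0744), rdgC (0.0569), CG13833 (0.0744), tim (0.0805) and Dr (0.0659) lost it, and without wild type 3C, CG8870 (0.124) and Him (0.0547) did.

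Across the comparisons, camera called 87 of 340 list results, and 58 of these calls held with an estimated correlation. Each of the 87 was also called by fry, which tests only whether the genes of a list move on balance in 1 direction. The difference between GFP positive and GFP negative cells itself differed between the 3 sets at 1109 probe sets.

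Overlap between genotypes was counted on all 13966 probe sets, with the number that independent calls give in brackets. Where 2 genotypes share wild type arrays, calls in the same direction, such as krimp, thw, Inx7, CG31248, H15 and Uhg1, may come from them. Their excess does not show a shared pathway. Such pairs were EGFR and FGFR (108 (2.24) rises, 91 (1.95) falls and no opposite call), EGFR and loss of spi (30 (3.19), 44 (2.86) and 15 (6.11) opposite), Ras and Arm+Ras (127 (4.74), 72 (3.09) and 1 (7.68)), Ras and Pnt (128 (13.4), 109 (14.7) and 33 (28.6)), Ras and Arm (85 (8.79), 79 (12.9) and 39 (22.6)) and Ras and Tkv (161 (15.3), 111 (11.7) and 29 (26.7)). Arm and loss of wg shared 251 (39.3) rises and 271 (94.7) falls, with 125 (123) opposite. Loss of Dl and Notch shared 6 (0.507) rises and 25 (2.24) falls, with 43 (2.16) opposite, lmd and Notch 9 (0.215) and 16 (0.986), with 8 (0.933), and lmd and Dl 18 (0.438) and 40 (1.41), with 2 (1.57). Pairs that share no control arrays were EGFR and Ras (65 (4.5) rises, 38 (4.24) falls and 12 (8.8) opposite), EGFR and Arm+Ras (60 (2.5), 47 (2.09) and 5 (4.65)), EGFR and Pnt (28 (7.05), 61 (9.95) and 36 (16.8)), Ras and Notch (10 (1.46), 4 (3.14) and 43 (4.91)) and Ras and Dl (26 (2.96), 30 (4.47) and 17 (7.76)).

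**Figure D3:**
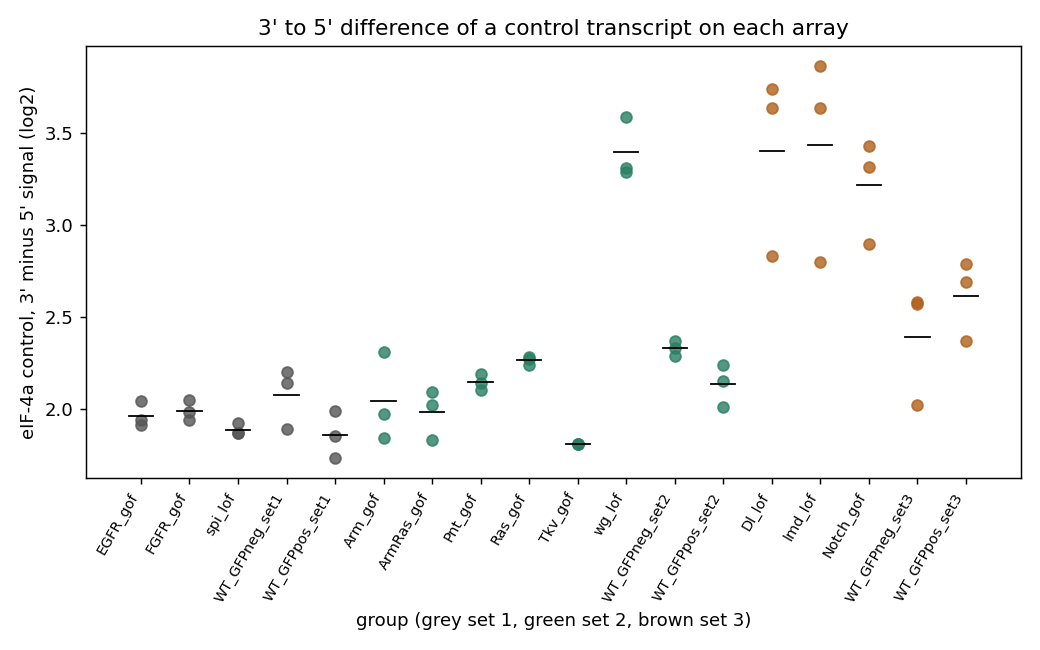
Log2 signal of the 3′ minus the 5′ probe set of the eIF-4a control transcript on each array (points) and the mean (lines) by group. The means of wg (3.40), Dl (3.40), lmd (3.43) and Notch (3.21) lie above those of the wild type GFP positive arrays of their sets (2.13 and 2.61), and that of Tkv (1.81) below.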

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

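The test with GFP negative cells, both tests of RNA quality and the tests of the wild type arrays of sets 1 and 2 were chosen after the results were seen, while the test of the wild type arrays of set 3 and the splits of the arrays were chosen before.

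The difference between GFP positive and GFP negative wild type cells itself differed between the 3 sets at 1109 probe sets by an F test. Of 100 splits drawn, the real one included, 1 gave as many calls, and the highest other gave 413, which argues against chance. Of the named genes, 17 differed between the sets. Set 3 had the smallest difference for Ndg (2.31 against 5.37 in set 1 and 4.70 in set 2, adjusted p = 0.000784), lmd (1.81 against 4.39 and 3.08, adjusted p = 0.00211) and rols (1.27 against 4.03 and 3.48, adjusted p = 0.001). The adjusted p of the difference between sets was 0.000114 for Npc2g, 0.00891 for Pxn, 0.00553 for org-1, 0.0203 for sing, 0.00273 for blow and 0.0186 for Him. It was 0.0497 for srp, 0.000207 for Ppn, 9.77e-05 for Act87E, 0.0173 for nkd, 0.0136 for salm, 0.00206 for Ance, 0.00541 for CycB and 0.00747 for RpS29. The wild type arrays of the 3 sets have the same age in their labels, and no technical or biological explanation was tested.

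Arm+Ras departed from the sum of Arm and Ras at 620 probe sets. Of 100 splits, 1 (the real one) gave as many calls, the highest other 374. The splits mix the real Arm and Ras differences, so they do not test the sum. No explanation was tested.

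Control probe sets, which are not part of the comparisons, differed between groups, and those with every array of a genotype above or below every wild type GFP positive array of its set follow. The 3′ minus 5′ signal of the eIF-4a control averaged 3.40 in wg against 2.13 in its wild type, and 3.40 in Dl, 3.43 in lmd and 3.21 in Notch against 2.61, and was lower in Tkv, 1.81 against 2.13. That of the actin control averaged 1.17 in Arm, 1.22 in Pnt and 1.38 in wg against 0.92, and 1.78 in Dl, 1.91 in lmd and 1.46 in Notch against 1.15, and was lower in Ras (0.75) and Tkv (0.58) than 0.92. That of the GAPDH control averaged 1.17 in wg against 0.16 and 2.67 in Notch against -0.47, and was lower than 0.16 in Pnt (-0.71), Ras (-0.02) and Tkv (-0.56). The hybridization controls averaged 9.99 in Arm, 9.84 in Arm+Ras, 10.18 in Pnt and 10.99 in wg against 9.32. Groups of 3 arrays were too small for a test of single arrays that stand apart.

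Loss of wg called 3709 probe sets, more than any other genotype here. With the 3′ minus 5′ covariate it called 793 (Pnt 1321, Arm 1226). GFP negative cells in the sort would raise the 178 probe sets lower in GFP positive cells of sets 1 and 3. Their median in wg was -0.58 (SE 0.08, probe sets not independent), with 12 called up and 77 down. That argues against such cells as the whole cause. RNA quality stays open, since 62.7% of the called probe sets changed in the direction of their slope on the 3′ minus 5′ difference in other groups, and within set 2 that difference and the genotype cannot be told apart. A response to lost Wg signalling stays open as untested.

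Probe sets called the same way in all genotypes of a set, which share wild type arrays, numbered 18 up and 33 down in set 1, 5 and 13 in set 2, and 5 and 12 in set 3, among them gcm, nkt, MtnA and CG13840. For 56.9% (set 1), 72.2% (set 2) and 82.4% (set 3), genotypes ranked nearer the wild type of other sets than their own wild type did. The probe sets were picked for differing from the set's wild type, so wild type arrays that stand apart stay open in each set. RNA quality in set 3 stays open, with 52.9% in the direction of the slope on the 3′ minus 5′ difference. The age of 6 to 8 h in the genotypes of set 3 against 5.5 to 7.5 h in their wild type also stays open as untested.

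For the comparison of GFP positive with GFP negative cells, 1 of 100 splits gave as many calls as the real 2332, and the highest other gave 1, which argues against chance. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 382 and 2 for EGFR, 308 and 1 for FGFR, 445 and 1 for spi, 966 and 3 for Arm, 641 and 0 for Ras, 338 and 1 for Arm+Ras, 1236 and 4 for Pnt, 1170 and 10 for Tkv and 3709 and 1 for wg. They were 331 and 0 for Dl, 144 and 1 for lmd, 207 and 1 for Notch, 224 and 1 for Arm+Ras against Ras, 1365 and 2 for Pnt against Ras, and 32 and 2 for EGFR against FGFR.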

How the results depend on the processing

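The fits without the letter A and with the 3′ minus 5′ covariate were chosen after seeing the data. The planned pseudocount on linear values did not apply, and 3 wild type arrays could not be split into 2 parts of at least 2. Only the 4 genes of wg given here reversed, and of the 9691 values of named called genes under the alternatives 8094 kept the call and 1593 lost it with the same sign. Quantile normalization moved no count of calls by more than 1.5 times. Dim probe sets are limited by signal over background, and each of the 17 counts among the brighter probe sets alone was within 1.5 times of the count over all. The cause of a changed count was not tested, except that fits with fewer arrays have less power by construction.

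Without the variance trend the calls were 165 for EGFR, 148 for FGFR, 203 for spi, 394 for Ras, 199 for Arm+Ras, 127 for Dl, 70 for lmd, 125 for Notch, 332 beyond the sum of Arm and Ras, 95 for Arm+Ras against Ras and 8 for EGFR against FGFR. With only the groups compared they were 137 for EGFR, 148 for FGFR, 408 for Arm, 713 for Pnt, 168 for Dl, 38 for lmd, 91 for Notch and 1 for EGFR against FGFR. Without the arrays with the letter A they were 112 for EGFR, 133 for FGFR, 127 for spi, 558 for Arm, 374 for Ras, 170 for Arm+Ras, 734 for Pnt, 343 beyond the sum, 133 for Arm+Ras against Ras, 873 for Pnt against Ras and 1 for EGFR against FGFR. At a change of at least 1.5-fold they were 1466 for the gate, 223 for EGFR, 190 for FGFR, 291 for spi, 406 for Ras, 219 for Arm+Ras, 127 for Arm+Ras against Ras and 18 for EGFR against FGFR, and fewer by construction. Set 3 on its own called 578 for the gate.

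With the replicate letter as a block, on the assumption that arrays with the same letter are paired, the calls were 709 for Dl, 385 for lmd, 424 for Notch and 52 for EGFR against FGFR. Letters stood apart in the controls. The poly-A controls averaged 2.66 for B against 8.18 for A and 7.14 for C in set 2, and 10.35 against 12.23 and 12.20 in set 1, with no overlap, so arrays of a letter may share a step of the processing. For A, in set 1 its hybridization controls lay above the means of 7.70 for B and 7.78 for C, and in set 3 its 3′ minus 5′ difference averaged 2.58 against 3.26 and 3.19. By the correlation of deviations from the group means, every array went best with the array of its own letter in EGFR, Pnt, Arm+Ras against Ras, Pnt against Ras and the gate in set 3, and not in the other 13 comparisons of 2 groups, and in none of the 18 did each of the 3 letters correlate above 0.1, so the counts of the report have no block. Within a letter there is 1 array per group, which allows no test.

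With the 3′ minus 5′ difference as a covariate the calls were 793 for wg, 563 for Tkv, 744 for Dl, 634 for lmd and 686 for Notch, and those of the other 7 genotypes stayed within 1.5 times. In wg the covariate nearly coincides with the genotype, so its values there are poorly determined by construction. The genes that reversed there were rols (1.16), aos (0.73), sna (0.03) and Mkp3 (-0.84), none of them called under it.

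Leaving out 1 array at a time gave 2057 to 2419 calls for the gate, 257 to 339 for EGFR, 175 to 316 for FGFR, 232 to 416 for spi, 639 to 1042 for Arm, 450 to 565 for Ras, 219 to 290 for Arm+Ras, 901 to 1137 for Pnt, 706 to 1197 for Tkv and 3219 to 3543 for wg. The ranges were 172 to 276 for Dl, 70 to 159 for lmd, 123 to 185 for Notch, 461 to 682 beyond the sum, 119 to 159 for Arm+Ras against Ras, 1030 to 1225 for Pnt against Ras, 10 to 39 for EGFR against FGFR and 904 to 1108 for the difference between sets. The report names the arrays that moved a count by over 1.5 times.

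Of the 87 camera calls, 83 held with the mean over the probe sets of a gene. Across probe sets, which are not independent replicates, log2 fold changes correlated at r = 0.54 between EGFR and FGFR over all probe sets, where a simulation without any change gave 0.50 for each pair that shares wild type arrays. Among the brighter probe sets r in such pairs was 0.62 for EGFR with FGFR, 0.32 for EGFR with spi, 0.39 for Ras with Pnt, 0.35 for Ras with Arm, 0.59 for Ras with Arm+Ras, 0.40 for Ras with Tkv, 0.36 for Arm with wg, 0.18 for Notch with Dl, 0.25 for lmd with Notch and 0.47 for lmd with Dl, so a positive r there does not show agreement. In pairs that share none it was 0.22 for EGFR with Ras, 0.28 for EGFR with Arm+Ras, 0.16 for EGFR with Pnt, -0.11 for Ras with Notch and 0.10 for Ras with Dl.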

Other observations

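The 3 tests of the spi pattern given here were chosen after the result was seen.

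With loss of spi, CG11600, Fmo-1 and Klp54D rose by 6.27, 5.24 and 5.18. A segment of chromosome carried with the mutation may hold such genes, and 11 of the 200 measured genes nearest to spi were called (5.5%) against 340 of 10642 elsewhere (3.19%), Fisher's exact p = 0.101. Over the whole chromosome of spi, in the gene order of the assembly Release 6 plus ISO1 MT, 166 of 4154 genes were called (4%) against 184 of 6591 on the others (2.79%), Fisher's exact p = 0.000791. That was the smallest of 78 such Fisher's exact tests looked at, over 13 comparisons, 3 sizes of change and 2 chromosomes, with adjusted p = 0.0617 over them. For changes of at least 2 on the log2 scale it was 30 of 4154 against 30 of 6591, Fisher's exact adjusted p = 0.494, so neither a segment nor other variants of that chromosome are decided. Wild type arrays of set 1 that stand apart would change the same probe sets in EGFR and FGFR, but 10.3% of the 78 probe sets with a change of at least 2 on the log2 scale were called in the same direction in both, which argues against them as the whole cause.

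Log2 fold changes across probe sets gave a covariance of 0.161 between EGFR and FGFR, against 0.114 in a simulation of shared wild type arrays. Between EGFR and Ras, which share none, it was 0.0404 with r = 0.12. It was 0.189 for Ras and Pnt (simulated 0.154), 0.192 for Ras and Arm+Ras (0.155), 0.31 for Arm and wg (0.154), and 0.158 for Notch and Dl (0.177). Between Ras and Notch, which share none, r was -0.03.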
